A study of Mus musculus with 18 samples.

How the data were processed

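RNA was measured in 18 libraries from 6 mouse pancreatic cancer lines grown from lung or liver metastases, with total RNA prepared for sequencing with a TruSeq kit per the labels' protocols (1.3 µg per library). Cells were kept in RPMI with 10% FBS and selected with puromycin for 48 h, per the labels. The genotype labels name p53 and p48-Cre alleles in all lines, and a floxed Sirt6 allele in all lines but 13-2. The authors deposited 1 table of CPM (counts scaled to the reads of a library) with 16383 genes, by Ensembl identifier and symbol, of which 32 symbols are repeated. The genome build was mm9, per the submitters' processing notes. The aligner, the counter, the gene annotation and any filter are not given in the sources used here, and no coordinates are printed because the reference at hand is of another build. Each listed column sums to 99.0% to 99.6% of the total that CPM implies. In each library the CPM values are whole multiples of the value of 1 read, and 100% of the values came out whole within 0.01 reads, which gave library totals of 8411436 to 25552912 reads. A gene with 3 reads lies at 0.117 to 0.357 CPM. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 33.0 over genes with at least 20 reads.

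Groups, cell lines and hairpins were taken from the labels as given. In line 6-2 the digits in the title codes of control and shRNA 1 are the reverse of those in the first 42-3 and first 42-2 sets, and Gstt1 was at 52.5 CPM in the 6-2 library labelled control and 0.358 CPM in that labelled shRNA 1. A culture set is the NT control and the knockdown libraries of the same line, and lines 42-3 and 42-2, with 2 NT controls each, were divided by the library code. There are 4 library codes, and control and knockdown carry different codes in lines 6-3 and 13-2. The pairing comes from the cell line named in the labels. As a check, the deviation of each knockdown library from its group mean was correlated across genes with that of its own control, which gave -0.36 to 0.70 (median 0.02), with 4 of 10 above 0.1.

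Genes at a CPM of at least 1 in at least 4 libraries were tested with limma 3.58.1 (trend, two-sided, Benjamini-Hochberg adjusted p of 0.05) on log2(CPM + 1) in R 4.3.3, with the culture set as a block. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The knockdown contrast was the mean of the hairpin effects, the lung and liver interaction was a further term, and lung and liver controls were compared on cell line means. The Gstt1 level was tested with an exact sign-flip permutation test. Gene lists were tested with camera (preset correlation 0.01, at least 5 tested members), with camera with an estimated correlation and with fry. Shared controls were examined with 100 simulations. Because whole reads could be recovered, edgeR 4.0.16 (quasi-likelihood test) was run on the recovered read counts, 100% of values being whole, as an alternative added after the data were seen. It called 0 genes for knockdown, 0 for each hairpin, 0 between the hairpins, 9 for the interaction and 0 between the sites. Between the sites it took the 8 NT controls as separate libraries, not as line means. Leaving out the 5 culture sets whose libraries differ in identity transcripts was also added then, as were leaving out a sixth set that differs at a limit of 1 CPM and running camera with an estimated correlation on both reduced groups of sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for tables, exact tests and plots.

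The design, the gene lists, the other alternatives and the naming rule were fixed before the data were examined. By that rule Gstt1 is named in each comparison, together with the 10 genes of largest rise and of largest fall among those past the threshold, with a mean CPM of at least 5 and the same direction in every set. Where fewer than 5 genes qualify, the 10 of smallest p are named. Of each list up to 4 members past the threshold, or otherwise the 2 of smallest p, are named. Fn1, Mki67 and Cdkn1a are given as values under knockdown. For the interaction the rule was read literally, so that the 10 genes of smallest p are named, with Sqle added after its value was seen. List members were named for knockdown and for lung against liver controls only. Some genes that the rule names are not reported here. The identity transcripts, their limits (10 CPM or 1 CPM, 10-fold, 2 of 7) and Gstt3, Cdkn2a, Cdkn2b and the genes without overlap between groups were chosen after the values were seen. Alternatives were pseudocounts of 0.5 and 2, no filter on low values, a CPM of at least 5, median-ratio rescaling, quantile normalization, robust variance estimation, no block, the cell line as the block, leaving out each set or line, leaving out lines 6-3 and 13-2, 1 knockdown term, and control libraries with a correlation within line.

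The limma fit was tested on simulated data with 200 changed genes, with counts drawn at the estimated spread (median dispersion 0.276). For knockdown, 20% of 2-fold and 97% of 8-fold changes were recovered among 12727 genes, for shRNA 1 8% and 92% among 12731, and for shRNA 2 4% and 83% among 12724. Between the hairpins 3% and 71% were recovered among 12709, for the interaction 0% and 41% among 12730, and between the sites 1% and 72% among 12157. The number of recovered genes in the wrong direction was 0 in each. Changed genes were drawn from those with a mean CPM of at least 5. Their spread followed a trend with level from the knockdown fit, not the spread of each gene. For the sites all lines were given the same mean, so differences between lines beyond that spread are absent. These shares may therefore overstate what the real data allow.

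The fixed lists cover glutathione metabolism, NRF2, extracellular matrix, matrix proteases, integrins, epithelial, mesenchymal, mitotic, DNA replication, cell cycle inhibitor, p53, interferon, integrated stress response, unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, inflammatory, TGF-beta, YAP and TEAD, RAS and MAPK, classical and basal pancreatic cancer, ribosomal protein, oxidative phosphorylation, histone and mitochondrial transcript genes, and markers of 6 other cell types. Of the 13 mitochondrial transcripts 0 are listed, so that list was not tested. Of the marker lists only the fibroblast list had 5 tested members, and members of the others are given as values.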

Results

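The transcriptomes of 6 mouse pancreatic ductal adenocarcinoma (PDAC) lines, each grown from a spontaneous metastasis, were measured by RNA-seq after knockdown of Gstt1, a theta-class glutathione S-transferase that conjugates glutathione to electrophiles. Lines 42-3 and 6-2 came from lung metastases and lines 42-2, G45-2, 6-3 and 13-2 from liver metastases. Cells were infected with lentivirus carrying an NT control hairpin, Gstt1 shRNA 1 or Gstt1 shRNA 2, selected with puromycin for 48 h and harvested after a further passage. The 18 libraries comprised 8 NT controls, 6 shRNA 1 and 4 shRNA 2 libraries. They formed 8 culture sets, each an NT control with the knockdowns of the same line, 3 from lung lines and 5 from liver lines. Lines 42-3 and 42-2 each contributed 2 sets, called first and second here by their library code. Both hairpins were present in 2 sets (G45-2 and 6-3), shRNA 1 alone in 4 and shRNA 2 alone in 2. Library depth, recovered from the step size of the deposited CPM values, ranged from 8411436 to 25552912 reads, so that 3 reads corresponded to 0.117 to 0.357 CPM. The 10 most abundant genes took 2.79% to 5.34% of a library.

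The first question was whether each hairpin lowered its target. Gstt1 (ENSMUSG00000001663) was lower than in the NT control of the same set in all 10 knockdown libraries, and the size of the difference varied widely. In the lung lines, Gstt1 went from 37.6 to 0.352 CPM with shRNA 1 in the first 42-3 set, from 38.8 to 0.238 CPM with shRNA 2 in the second 42-3 set, and from 52.5 to 0.358 CPM with shRNA 1 in line 6-2. In line 13-2 it went from 24.3 to 0.283 CPM with shRNA 1. In line 6-3 the NT control held 25.4 CPM, the shRNA 1 library 19.2 CPM (75.4% of control) and the shRNA 2 library 0.250 CPM (0.982%). In line G45-2 the NT control held 43.8 CPM, the shRNA 1 library 23.9 CPM (54.5%) and the shRNA 2 library 5.15 CPM (11.8%). Line 42-2 expressed little Gstt1 at the start. Its first set went from 2.67 to 0.373 CPM with shRNA 1 and its second from 0.616 to 0.0687 CPM with shRNA 2, which was 8 reads against 1 read.

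**Figure D1:**
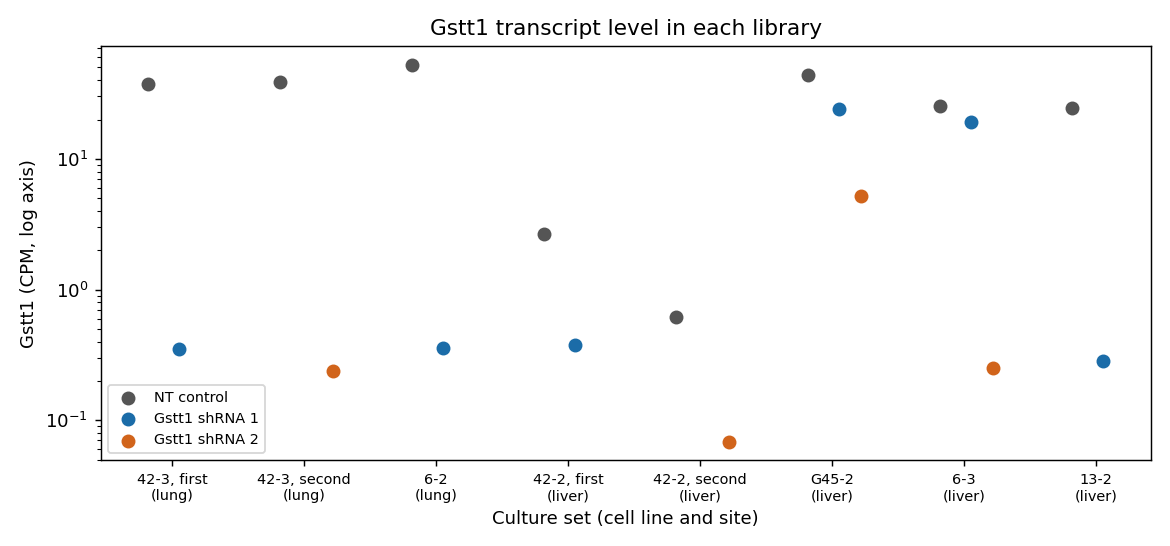
Gstt1 level (CPM, log axis) in each library, by culture set, with 1 point per library for the NT control, shRNA 1 and shRNA 2. Every knockdown point lies below the control of its set, from 23.9 CPM in the G45-2 shRNA 1 library to 0.0687 CPM in the second 42-2 set.

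Averaged over culture sets, the log2(CPM + 1) difference from the own control was -3.21 ± 1.85 (SD, n = 8 sets), lower in 8 of 8 sets. The exact two-sided sign-flip permutation test gave p = 0.00781, the smallest that 8 sets allow. With the 6 cell lines as units the difference was -3.30 (exact permutation p = 0.0313, the smallest that 6 lines allow). With the 5 sets of differing identity transcripts, described next, left out it was -1.62 ± 0.92 (SD, n = 3 sets; exact permutation p = 0.25, the smallest that 3 sets allow), and -2.13 ± 0.38 with the second 42-2 set also left out (SD, n = 2 sets; exact permutation p = 0.5, the smallest that 2 sets allow). In the limma model across genes the change was -3.27 (SE 0.67, adjusted p = 0.0820) and did not pass. For the libraries with 1 to 3 Gstt1 reads the exact 95% counting interval of the ratio to control was 0.251% to 83.2% in the second 42-2 set (1 read), 0.0740% to 2.22% in the second 42-3 set (2 reads) and 0.202% to 2.89% in 6-3 shRNA 2 (3 reads). These intervals cover counting error only. The closely related paralog Gstt3 was at 19.0 ± 14.3 CPM in NT controls (SD, n = 8) and 3.67 ± 3.95 CPM in knockdowns (n = 10), a log2 change of -2.38 (SE 0.57, limma adjusted p = 0.109) that did not pass. How reads shared between such paralogs were assigned is not given in the sources used here, so the separate levels of Gstt1 and Gstt3 are uncertain.

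Transcripts that mark the identity of a line were compared between the libraries of each set. These were the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, the X-inactivation RNA Xist, and Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes often lost together in PDAC. In the first 42-3 set Ddx3y was at 222 CPM in the NT control and 0 in the library labelled shRNA 1, while Xist was at 0.0736 and 197 CPM. In the second 42-3 set Ddx3y was at 98.3 and 0.119 CPM and Cdkn2b at 101 and 0 CPM. In line 6-2 Ddx3y was at 216 and 1.08 CPM and Cdkn2b at 238 and 0 CPM. In line 13-2 Cdkn2b was at 211 and 0.0706 CPM, and in the first 42-2 set at 175 and 8.43 CPM. In these 5 sets at least 2 of the 7 transcripts reached 10 CPM in 1 library and were at least 10-fold lower in its partner. In G45-2 only Kdm5d did so (29.8 CPM against 0 with shRNA 1 and 0.0621 with shRNA 2), and in 6-3 none did. In the second 42-2 set all 4 Y-linked transcripts were over 10-fold lower in the knockdown library but under 10 CPM in the control, Eif2s3y at 4.08 and 0.0687 CPM and Ddx3y at 3.00 and 0.0687 CPM. With a limit of 1 CPM this set differs too, and 2 sets, G45-2 and 6-3, are left. The transcripts and limits of this comparison were chosen after the values had been seen. All 3 lung sets are among the 5. Nothing in the labels says that the libraries are independent cultures beyond their lines and sets, so the p-values measure the spread between these samples, which may be technical.

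**Figure D2:**
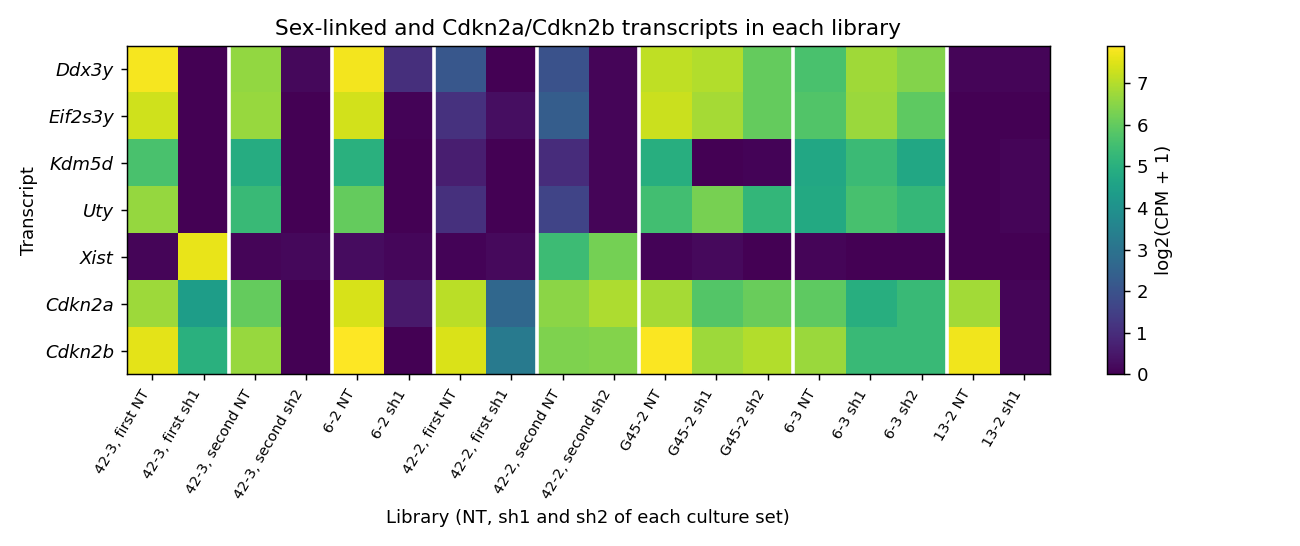
Level of 4 Y-linked transcripts, Xist, Cdkn2a and Cdkn2b as log2(CPM + 1), shown by colour, in each of the 18 libraries, with white lines between culture sets. The NT control and knockdown libraries of both 42-3 sets, 6-2, the first 42-2 set and 13-2 differ in at least 2 of the 7 transcripts at a limit of 10 CPM, and the second 42-2 set also does at a limit of 1 CPM.

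The next question was which transcripts changed with Gstt1 knockdown, taking the mean of both hairpins against the controls of the same sets. Of 12931 genes tested, 5 passed in limma, 1 higher and 4 lower. Slc39a4 (ENSMUSG00000063354), a zinc importer, fell from 274 ± 253 CPM in NT controls (SD, n = 8) to 34.5 ± 45.6 with shRNA 1 (n = 6) and 43.7 ± 52.1 with shRNA 2 (n = 4), a log2 change of -3.72 (SE 0.50). Tnip1 (ENSMUSG00000020400), which restrains NF-kB signalling, fell from 212 ± 72.2 to 95.7 ± 23.0 and 94.0 ± 16.6 CPM, a log2 change of -1.12 (SE 0.15). Kif21b, a kinesin motor, fell from 43.8 ± 25.9 to 12.0 ± 14.8 and 11.5 ± 9.11 CPM, a log2 change of -2.47 (SE 0.35). Vtcn1 (ENSMUSG00000051076), an inhibitory ligand of the B7 family, fell from 4.70 ± 3.76 to 0.128 ± 0.183 CPM with shRNA 1 and had no reads in any of the 4 shRNA 2 libraries, where 3 reads would be at most 0.357 CPM. Arhgap31, a GTPase-activating protein for Cdc42 and Rac1, rose from 2.01 ± 2.06 to 34.0 ± 34.9 and 29.8 ± 13.8 CPM, a log2 change of 3.50 (SE 0.46). Each of the 5 moved in the same direction in 8 of 8 sets. The adjusted p was 0.0432 for Kif21b and 0.0372 for the other 4. The change of Slc39a4 was -2.36 with the 5 sets of differing identity transcripts left out and -1.83 with the second 42-2 set also left out.

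The 5 genes next in order of p also kept 1 direction in 8 of 8 sets, but did not pass (limma adjusted p = 0.0512 each). The immediate early transcription factor Fos had a log2 change of -2.86 (SE 0.44), the oxidative stress-induced Osgin1 -1.31 (SE 0.20) and the kinesin subunit Kif3a -0.90 (SE 0.14). The polycomb component Bmi1 had a change of 0.95 (SE 0.15) and the zinc finger gene Zfp367 of 1.25 (SE 0.20). The proliferation marker Mki67 was at 76.7 ± 32.5 CPM in NT controls and 242 ± 84.0 CPM in knockdowns (SD, n = 8 and 10), higher in 8 of 8 sets, with an adjusted p of 0.0692. Fibronectin (Fn1) had a log2 change of 0.26 (SE 0.44, adjusted p = 0.804) and the cyclin-dependent kinase inhibitor Cdkn1a of 1.57 (SE 0.72, adjusted p = 0.290). Their sign turned to -0.04 for Fn1 without the first 42-3 set and to -0.95 for Cdkn1a with the 5 sets of differing identity transcripts left out. The edgeR test on the recovered reads called 0 genes, with 1959 at an unadjusted p under 0.05 against 2216 in limma. The count fell to 0 without any of the sets 13-2, 6-2, 6-3, the first or second 42-2 set or the second 42-3 set, to 3 without G45-2, and was 8 without the first 42-3 set. It was 0 of 11723 genes with the 5 sets of differing identity transcripts left out (1314 at an unadjusted p under 0.05 in limma), 0 of 11334 with the second 42-2 set also left out (1469), and 84 without the culture set as a block. Of the genes at an unadjusted p under 0.05, 41.1% were higher under knockdown, and 52.3% with quantile normalization.

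Of 26 gene lists fixed before the data were examined, 7 passed camera with a preset correlation of 0.01 under knockdown. The mitotic genes, which drive chromosome segregation and cytokinesis, rose as a group: all 30 were higher, with a median log2 change of 1.02 (camera adjusted p = 1.03e-18; adjusted p = 0.489 with an estimated correlation). None of the 30 passed over all genes, and 24 passed upward adjusted over the list alone. Ckap2, a spindle protein, was at 51.4 ± 17.3 CPM in NT controls and 117 ± 18.8 CPM in knockdowns (SD, n = 8 and 10). The DNA replication genes also rose as a group, with 35 of 36 higher and a median of 0.69 (adjusted p = 1.62e-12; adjusted p = 0.579 with an estimated correlation). None passed over all genes and 10 passed adjusted over the list alone. Within it the replicative helicase subunit Mcm4 had a log2 change of 0.95 (SE 0.26) and the histone mRNA binding protein Slbp of 0.69 (SE 0.21).

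The inflammatory and NF-kB genes fell as a group, with 34 of 36 lower and a median of -1.16 (camera adjusted p = 5.77e-10; adjusted p = 0.489 with an estimated correlation). None passed over all genes and 14 passed downward adjusted over the list alone. The granulocyte growth factor Csf3 was at 119 ± 124 CPM in NT controls and 19.0 ± 40.9 CPM in knockdowns, and the apoptosis inhibitor Birc3 at 36.0 ± 23.3 and 14.6 ± 7.89 CPM (SD, n = 8 and 10). The classical pancreatic cancer genes, which mark the gastrointestinal-like subtype of PDAC, fell with 21 of 22 lower (median -1.37, adjusted p = 5.52e-07; adjusted p = 0.489 with an estimated correlation). The tight junction gene Cldn18 had a log2 change of -3.83 (SE 0.90) and the protease Ctse of -2.80 (SE 0.72), and 10 members passed adjusted over the list alone, 0 over all genes. The epithelial genes fell with 25 of 28 lower (median -0.96, adjusted p = 5.18e-06; adjusted p = 0.489 with an estimated correlation), 8 passing adjusted over the list alone and 0 over all genes. The mucin Muc1 had a log2 change of -3.06 (SE 0.52) and the transcription factor Elf3 of -1.88 (SE 0.36). By library, the epithelial median was lowest in the first 42-3 set (-3.04), where the fibroblast markers Col3a1 and Pdgfrb went from 0.0736 to 3625 CPM and from 0.442 to 219 CPM. In the second 42-2 set, with Col3a1 at 2681 and 6083 CPM in control and knockdown, the epithelial median was -0.11.

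Oxidative phosphorylation genes fell with 48 of 52 lower but by less (median -0.34, camera adjusted p = 3.81e-06; adjusted p = 0.766 with an estimated correlation), the complex I subunit Ndufa6 with a log2 change of -1.02 (SE 0.25). The other glutathione transferases and glutathione metabolism genes fell with 33 of 40 lower (median -0.37, adjusted p = 0.00189; adjusted p = 0.489 with an estimated correlation), Gsta3 going from 4.38 ± 3.62 to 1.16 ± 1.68 CPM (SD, n = 8 and 10). Neither list had a member past the threshold over all genes or adjusted over the list alone. By fry, which tests for a common direction, none of the 26 lists passed, the smallest adjusted p being 0.0851 for the inflammatory genes. The per-set median of the mitotic list was higher than control in 6 of 8 sets, at 1.02 ± 1.22 (SD, n = 8). That of the inflammatory list was lower in 7 of 8, at -0.87 ± 0.91. The DNA replication median (0.63 ± 0.88) was below control in both 42-3 sets (-0.84 and -0.21). The epithelial median (-0.93 ± 1.24) was above control in 6-2 (0.61) and the first 42-2 set (0.37). The classical median (-1.49 ± 1.93) was lower in 8 of 8, most in 6-2 (-5.24) and the first 42-2 set (-3.81). In 6-3, Gstt1 was at 75.4% of control with shRNA 1 and 0.982% with shRNA 2. The mitotic medians there were 1.90 and 2.23 and the inflammatory medians -1.79 and -2.15. In both 42-3 sets, 6-2 and 13-2, Gstt1 was at 0.613% to 1.16% of control. The mitotic median in these sets ranged from -1.04 to 2.35 and the inflammatory median from -0.36 to 0.39. With the 5 sets of differing identity transcripts left out, 17 of 25 lists passed camera, among them the same 7 in the same direction, but none held with an estimated correlation (smallest adjusted p = 0.197). The medians in that fit were -0.59 for the classical list and -0.16 for oxidative phosphorylation. With the second 42-2 set also left out 15 lists passed, the same 7 among them, and 0 with an estimated correlation (smallest adjusted p = 0.406). In the fit of all sets the remaining 19 lists did not pass, their adjusted p ranging from 0.0584 for p53 targets to 0.959 for matrix proteases and their inhibitors. Of the markers of other cell types, the macrophage gene Cd68 was at 9.19 ± 4.48 and 5.03 ± 3.57 CPM, and the fibroblast collagen Col3a1 at 384 ± 937 and 1178 ± 2064 CPM, in NT controls and knockdowns (SD, n = 8 and 10). The 5 fibroblast markers tested had a camera adjusted p of 0.522.

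**Figure D3:**
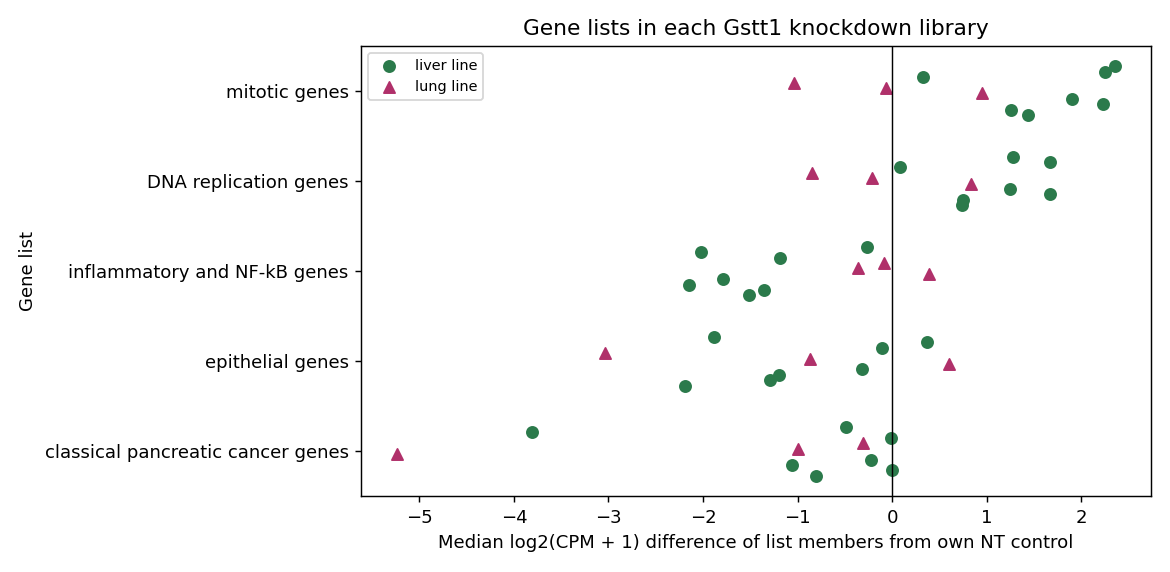
Median log2(CPM + 1) difference of the members of 5 gene lists from the NT control of the same set, with 1 point per knockdown library, circles for liver lines and triangles for lung lines. The mitotic list lies between -1.04 in the first 42-3 set and 2.35 in 13-2, and every liver library lies above 0 for it.

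Each hairpin was then compared with the controls separately. With shRNA 1, Osgin1 was at 68.1 ± 31.1 CPM (SD, n = 6) against 254 ± 162 in NT controls (n = 8), a log2 change of -1.85 (SE 0.24) with the smallest adjusted p of 0.0693. Muc1 (-3.67, SE 0.60) and Hr, a transcriptional corepressor (2.32, SE 0.40), were also among the 10 genes of smallest p. With shRNA 2, Arhgap31 (3.69, SE 0.63), the choline transporter-like Slc44a3 (-4.17, SE 0.82), the Schlafen gene Slfn2 (-3.24, SE 0.67), the pyridoxal kinase Pdxk (-1.40, SE 0.29) and the lipopolysaccharide-binding protein Lbp (-4.35, SE 0.92) were among the 10, each with an adjusted p of 0.641. No gene passed in limma for shRNA 1 (0 of 12931, 2077 at an unadjusted p under 0.05) or shRNA 2 (0, with 834), and edgeR called 0 in each. For shRNA 1 the count was 2 without G45-2 and 10 without the culture set as a block. The Gstt1 change was -2.67 (SE 0.77, adjusted p = 0.181) with shRNA 1 and -3.86 (SE 0.92, adjusted p = 0.715) with shRNA 2. With the 5 sets of differing identity transcripts left out the fit gave -0.11 and -2.62. The differences from the own control with shRNA 1 in the sets that remain were -0.85 in G45-2 and -0.39 in 6-3, so that -0.11 does not describe the change within these sets. That fit also takes in the second 42-2 set, which has shRNA 2 only and a control at 0.616 CPM. By camera, 8 of 26 lists passed for shRNA 1 and 11 for shRNA 2. None of these held with an estimated correlation, the smallest adjusted p being 0.680 and 0.316.

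The difference between the hairpins was tested directly. The gene of smallest p was Dhtkd1, a mitochondrial dehydrogenase component, at 0.431 ± 0.550 CPM with shRNA 1 (SD, n = 6) and 2.15 ± 1.87 with shRNA 2 (n = 4). Osgin1 was 1.08 (SE 0.32) higher on the log2 scale with shRNA 2, while the RNA sensor Ifih1 (-1.67, SE 0.51), the gelatinase Mmp9 (-2.83, SE 0.99) and the class I antigen H2-K1 (-1.29, SE 0.47) had negative differences. None passed: limma called 0 of 12931 genes, with 64 at an unadjusted p under 0.05 and a smallest adjusted p of 0.9999, and edgeR called 0. The interferon response list was lower with shRNA 2 by camera (adjusted p = 3.25e-19), 1 of 12 lists that passed, and none of the 12 held with an estimated correlation (smallest adjusted p = 0.173). The 2 sets with both hairpins differed in this. The interferon medians with shRNA 1 and shRNA 2 were -0.22 and -0.19 in G45-2, and 0.29 and -0.49 in 6-3. Across genes, the changes of the hairpins correlated with r = 0.785 in the fit of all libraries, where simulated groups with no effect against the same controls gave 0.236. The covariance was 0.312 against a simulated 0.0581. The simulated groups were unchanged from their controls, so they account for shared controls only. Mismatched libraries, which could raise both values, are not covered. In sets that share no library, 4 with shRNA 1 only against 2 with shRNA 2 only, Pearson's r was 0.399 and Spearman's rho 0.327, and 61.1% of genes had the same sign. These sets share lines 42-3 and 42-2, 5 of the 6 are sets of differing identity transcripts, and no value without an effect was simulated for them. Genes are not independent replicates, so these values describe the libraries. At an unadjusted p under 0.05, 227 genes were higher and 378 lower with both hairpins, where independent lists would share 20.2 and 48.9, and part of this excess may come from the shared controls.

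The series names liver and lung lines, and the difference between them in the knockdown effect was tested as an interaction. The 3 lung sets come from 2 lines and the 5 liver sets from 4 lines. The p-values and SDs here treat sets as units, so they do not measure the spread between lines alone. Of 12931 genes, 24 passed in limma, 10 with a more positive and 14 with a more negative effect in lung lines (2293 at an unadjusted p under 0.05). Axl, a receptor tyrosine kinase, was 3.44 ± 0.18 higher than control on the log2 scale in the 3 lung sets and 0.32 ± 0.50 in the 5 liver sets (SD), a difference of 3.10 (SE 0.38, adjusted p = 0.0116). The TGF-beta co-receptor Tgfbr3 was at 5.68 ± 1.57 and -0.76 ± 1.30, the phospholipase Plcb4 at 4.38 ± 0.17 and -0.71 ± 1.11, and the Rag GTPase Rragd at 3.50 ± 0.67 and -1.74 ± 0.91. The glutamate transporter Slc1a2 was at -6.34 ± 1.37 and -0.26 ± 0.57, Spns3 at -4.62 ± 0.72 and -0.42 ± 0.45 and Sh3bgrl3 at -2.24 ± 0.54 and 0.22 ± 0.34. The Y-linked Eif2s3y (-7.10 ± 0.37 and -0.67 ± 1.07), Ddx3y (-6.99 ± 0.71 and -0.75 ± 1.30) and Uty (-6.02 ± 0.65 and -0.33 ± 0.93) also passed. The Gstt1 change did not pass for a difference, at -5.05 ± 0.23 and -2.11 ± 1.39 (adjusted p = 0.207).

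By camera, 9 of 26 lists passed for the interaction. The mitotic genes (0 of 30 with a more positive effect in lung lines, median -1.73, adjusted p = 1.26e-15) and the cholesterol synthesis genes (0 of 24, median -1.73, adjusted p = 8.14e-14) had lower effects in lung lines, and the inflammatory and NF-kB genes higher ones (28 of 36, median 1.44, adjusted p = 0.000368). With an estimated correlation each of these had an adjusted p of 0.494. By fry only cholesterol synthesis passed (adjusted p = 0.0393). Sqle, the squalene epoxidase of that list, passed over all genes, and 17 members passed adjusted over the list alone. No mitotic gene passed over all genes and 26 passed adjusted over the list alone. Each of the 3 lung sets is among the 5 in which the identity transcripts differ, so the interaction could not be fitted without those sets. In edgeR 9 genes passed, all of them among the 24. The count was 0 without the first 42-3 set, 3 without the second 42-3 set, 6 without G45-2, 15 without 6-3, 39 without 6-2, 48 without the first 42-2 set, 0 without lines 6-3 and 13-2 and 2 without the culture set as a block.

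Lung and liver lines were also compared in the NT controls alone, with the cell line as the unit (2 lung, 4 liver). The 2 NT controls of line 42-2, averaged here as 1 line, differed in Xist (0.0494 and 41.7 CPM), and their deviations from the group mean correlated at -0.05 across genes. Of 12050 genes 1 passed in limma. The 9 genes next in order of p did not pass, with an adjusted p of 0.0556 each. Among them Slc1a2 was at a log2(CPM + 1) of 6.36 ± 0.70 in lung and 0.95 ± 0.62 in liver lines (SD, n = 2 and 4 lines) and Sh3tc2 at 4.99 ± 0.24 and 0.66 ± 0.63. Axl (6.87 ± 0.03 and 9.69 ± 0.42), the nitric oxide synthase Nos2 (2.17 ± 1.11 and 6.35 ± 0.32), the actin-bundling Fscn1 (5.04 ± 1.17 and 9.25 ± 0.40) and the iron-binding lipocalin Lcn2 (4.27 ± 0.26 and 8.82 ± 0.93) had higher values in liver lines, as did Gramd1a, Scarf2 and Lphn2. Gstt1 was at 5.52 ± 0.32 and 4.04 ± 1.87 (adjusted p = 0.572). In limma 1606 genes had an unadjusted p under 0.05. The edgeR fit, which took the 8 NT controls as separate libraries instead of the line as the unit, called 0. The count was 0 without line 42-2, 42-3 or 6-2, 5 without G45-2 and 160 without 6-3.

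Of 25 lists tested between the sites, 6 passed camera. The mitotic genes (30 of 30 higher in lung lines, median 1.28, adjusted p = 6.55e-13), DNA replication genes (36 of 36, median 0.79, adjusted p = 2.93e-09), cholesterol synthesis genes (23 of 24, median 1.04, adjusted p = 6.25e-07) and oxidative phosphorylation genes (43 of 52, median 0.24, adjusted p = 0.000177) were higher in lung lines. The inflammatory and NF-kB genes (27 of 35 lower, median -1.32, adjusted p = 2.55e-05) and the matrix proteases and their inhibitors (22 of 27 lower, median -0.51, adjusted p = 0.0122) were lower. The same NT controls enter the interaction with the opposite sign, so the site and interaction comparisons are not independent. The mitotic, cholesterol synthesis and inflammatory lists, and the genes Slc1a2 and Axl, had opposite signs in them. With an estimated correlation each of the 6 lists between the sites had a camera adjusted p of 0.864. None passed by fry, and no member passed over all genes. Adjusted over the list alone, 3 inflammatory genes were higher and 11 lower, and no member of the other 5 lists passed. Examples were the spindle checkpoint activator Cdc20 (7.46 ± 0.13 in lung and 6.05 ± 0.69 in liver lines on the log2 scale), the sterol demethylase Cyp51 (8.35 ± 0.18 and 6.30 ± 1.00) and the chemokine Cxcl16 (5.47 ± 0.01 and 7.43 ± 0.44). Markers of other cell types did not pass, with Aqp5 at 1.96 ± 0.29 and 5.85 ± 2.22 and Pdgfra at 1.16 ± 0.15 and 4.56 ± 2.28.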

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

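All tests of explanations in this part, the edgeR fits, the identity transcript comparison and the fits without 5 culture sets were chosen after the results were seen.

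In both 42-3 sets, 6-2, the first 42-2 set and 13-2, control and knockdown differed in at least 2 of 7 identity transcripts at a limit of 10 CPM, and in the second 42-2 set they did at a limit of 1 CPM. Loss of the Y chromosome within the first 42-3 set is argued against by Xist at 197 CPM in the knockdown library, against 0.0736 CPM in its control. Depletion of Gstt1 by itself stays open for the 5 sets as a whole. It does not account for a difference between the knockdown libraries of the first and second 42-3 sets. With Gstt1 at 0.938% and 0.613% of control there, Xist was at 197 and 0.119 CPM and Cdkn2b at 31.5 and 0 CPM. Ddx3y was low in both, at 0 and 0.119 CPM. Of the shRNA 2 libraries, 3 of 4 kept Cdkn2b above 10% of their own control, but these are the 3 sets outside the 5. The second 42-2 set, 1 of them, differed in its low Y-linked transcripts and had only 8 Gstt1 reads in its control. In 6-3 with shRNA 2, Gstt1 was at 0.982% of control and 0 of the 7 transcripts differed, so in that line depletion did not bring the pattern. A library from another cell line than its label may account for the pattern, and this stays open too. In the 5 sets, 4 of the 5 knockdown libraries were closer to the control of another set than to their own. So were 2 of 5 in the remaining sets, both of them from G45-2. Across genes, deviations from the group means correlated at 0.62 between the second 42-3 shRNA 2 library and the 13-2 shRNA 1 library and at -0.16 between the former and its own control, and at 0.35 between the 6-2 and first 42-2 shRNA 1 libraries and at -0.36 between the 6-2 library and its own control.

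Mitotic genes were higher and inflammatory genes lower under knockdown by camera with the preset correlation. Neither list held with an estimated correlation (camera adjusted p = 0.489 each) or by fry, and no member passed over all genes. The mitotic median was below control in both 42-3 sets (-1.04 and -0.06), and the inflammatory median was above control in 6-2 (0.39). The pattern did not rest on the 5 sets with differing identity transcripts alone. Without them the per-set median was 1.24 ± 0.87 for the mitotic and -1.53 ± 0.40 for the inflammatory list (SD, n = 3 sets). With the second 42-2 set also left out, for the limit of 1 CPM, it was 1.70 ± 0.51 and -1.70 ± 0.37 (SD, n = 2 sets). These values cannot exclude mismatched libraries as a cause. Both G45-2 knockdown libraries were closer to the control of another set than to their own, and control and knockdown carry different library codes in 6-3. Library codes that differ between control and knockdown could contribute, since without those sets the values were 0.63 ± 1.15 and -0.78 ± 0.91 (SD, n = 6 sets), smaller than their spread, and this stays open. An effect of Gstt1 depletion stays open as a biological explanation, and the depth of knockdown was not tested against the lists. In 6-3, with Gstt1 at 75.4% and 0.982% of control, the mitotic median was 1.90 and 2.23. The inflammatory median there was -1.79 and -2.15. At 54.5% and 11.8% in G45-2 they were 1.25 and 1.44, and -1.36 and -1.52. In both 42-3 sets, 6-2 and 13-2, Gstt1 was at 0.613% to 1.16% of control. The mitotic median in these sets ranged from -1.04 to 2.35 and the inflammatory median from -0.36 to 0.39.

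The knockdown effect differed between lung and liver lines for 24 genes, as tested by an interaction term. That test takes culture sets as units, 3 from 2 lung lines and 5 from 4 liver lines. The log2 differences were -6.54 for Eif2s3y, -6.07 for Slc1a2, -5.81 for Uty, -6.38 for Ddx3y, 3.10 for Axl, 5.01 for Plcb4, -2.47 for Sh3bgrl3, -4.21 for Spns3, 5.16 for Rragd and 6.34 for Tgfbr3. Of the 4 Y-linked transcripts 3 are among the 24. Differing identity transcripts in the lung culture sets may be the cause, and this cannot be told apart from a site difference because 0 lung sets are left once these sets are removed. A difference between the lung and liver NT controls also enters the interaction term, with the opposite sign. The 15 splits of the lines are too few for a share under 0.05: 1 of the 15, the real one, gave 24 genes, and the highest other gave 14.

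For knockdown, 2 of 100 splits within sets, the real one included, gave as many as the 5 genes. That share is under 0.05, but the 1 other split gave 11 genes, more than the real one, so chance is not excluded for the count. The count was also 0 in edgeR, with no filter on low values and without any of 6 of the sets, so the share does not make the 5 calls secure. For shRNA 1, shRNA 2 and the difference between hairpins the real count is 0, which all 100 splits match by construction, so these counts say nothing about chance. Their highest counts in other splits were 329, 1 and 4, and 329 may point to a structure of the samples, which was not tested. At an unadjusted p under 0.05, shRNA 1 had 2077 genes, reached by 6 of 100 splits (highest other 2623), shRNA 2 had 834, reached by 1, the real one (highest other 718), and the difference had 64, reached by 98 (highest other 1179). Between the sites, 4 of 15 splits gave as many as the real 1 gene, the splits are too few for a share under 0.05, and the highest other gave 64, which may point to a structure of the samples, also not tested.

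In 29 of 437 groups of libraries 1 library lay far from the others, by its gap to the nearest library as a share of the range. Chance flags about 1 in 20 groups if the libraries of a group are draws from 1 normal distribution. Each group pools different lines, and libraries were not compared with their own controls here, so a flag may mark a line. For Cldn18 the change from the own control in 6-3 was -0.04. Among shRNA 1 libraries, 13-2 was highest for Vtcn1 (0.757), and 6-3 for Muc1 (0.822) and Cldn18 (0.948, at 421 CPM against at most 0.461). G45-2 was lowest with shRNA 1 for Fscn1 (0.670), Gramd1a (0.695), Scarf2 (0.741) and Gata4 (0.662), and the first 42-3 set for Etv4 (0.723). Among shRNA 2 libraries, G45-2 was highest for Gstt1 (0.911), Slc44a3 (0.883), Sh3tc2 (0.873), Plat (0.895) and Cenpf (0.853) and lowest for Gata4 (0.845). The second 42-3 set was highest for Lbp (0.951, at 24.0 CPM against at most 0.248), Btg2 (0.843) and Krt16 (0.925) and lowest for Mcm4 (0.948). The second 42-2 set was highest for Otx1 (0.951) and lowest for Bhlhe40 (0.864) and Krt8 (0.904, at 7.15 CPM against 1213 to 2071). Line 6-3 was highest for Spns3 (0.978) and Cldn18 (0.978, at 517 CPM against at most 0.412) and lowest for Ndufa6 (0.931). Among NT controls, 13-2 was highest for Rpl34 (0.673) and lowest for Phlda3 (0.556), the first 42-3 set highest for Hist2h4 (0.537) and lowest for Ier3 (0.555), and 6-2 highest for Apoa1 (0.574).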

How the results depend on the processing

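The edgeR fits and the fits without the 5 sets of differing identity transcripts, or without these and the second 42-2 set (6 sets), were chosen after the data were seen. For the 5 knockdown genes the count was 0 with no filter on low values, 0 without lines 6-3 and 13-2, 0 with edgeR (1959 at an unadjusted p under 0.05), 0 with the 5 or 6 sets left out, 51 with the cell line as the block, 84 with no replicate block, 91 with 1 knockdown term, and 0 to 8 when each set was left out. For shRNA 1, 0 in the limma fit, it was 2 with the cell line as the block, 10 with no replicate block and 0 to 2 when each set was left out, and for shRNA 2 and the difference between hairpins 0 to 0. For the 24 interaction genes it was 41 with quantile normalization, 2 with no replicate block, 0 without lines 6-3 and 13-2, 9 with edgeR and 0 to 48 when each set was left out. For the 1 gene between the sites it was 0 with a pseudocount of 0.5, 2 with a pseudocount of 2, 3 with no filter on low values, 15 with a CPM of at least 5, 60 with control libraries and a correlation within line, 0 with edgeR and 0 to 160 when each line was left out. The block changed no other count of genes past the threshold by over 1.5 times. With no replicate block, the lists that passed camera went from 11 to 7 for shRNA 2 and from 12 to 7 between the hairpins. The Gstt1 difference was -3.59 to -2.92 when each set was left out, -1.62 with the 5 sets left out and -2.13 with the 6 left out. Under knockdown, where 7 of 26 lists passed, the number was 0 with an estimated correlation, 17 with the 5 sets left out, 15 with the 6 left out, 0 in each of these with an estimated correlation, and 7 to 10 when each set was left out. The same 7 were among those that passed in each of these fits with the preset correlation. Of the 6 lists between the sites 0 passed with an estimated correlation. The correlation of the hairpin effects was 0.40 in sets that share no library. None of the results that passed before these changes reversed, and the cause of the changes was not tested. The p53 targets and cholesterol synthesis genes, which had not passed under knockdown in the fit of all sets, passed camera in opposite directions in different fits. Of the named genes under each alternative, 3120 results kept their side of the threshold, 117 lost it, 78 gained it, and 17 changed sign without passing in either fit. For lists the numbers were 315, 27 and 26, and 40 that had not passed changed direction. The interaction with the 5 or 6 sets left out was not run, since no lung set remains. Genes under 0.117 to 0.357 CPM, depending on the library, had fewer than 3 reads.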

Other observations

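The comparison of genes without overlap between groups and the fits without the sets of differing identity transcripts were chosen after the data were seen. In 24 of 12931 genes the 8 NT controls and the 10 knockdown libraries did not overlap, 13 higher and 11 lower under knockdown, where chance gives 0.00457% of genes, or 0.591 genes, if libraries were independent. Foxm1, a transcription factor of the G2 and M phases, was at 68.3 ± 27.0 CPM in NT controls and 184 ± 69.1 CPM in knockdowns (SD, n = 8 and 10), and the spindle protein Numa1 at 196 ± 19.9 and 321 ± 55.6 CPM. Smad5, a mediator of BMP signalling, was at 69.5 ± 9.76 and 115 ± 25.4 CPM. Among the lower genes, Sat2 was at 11.6 ± 5.64 and 2.18 ± 1.71 CPM, the G protein subunit Gnb5 at 38.9 ± 10.1 and 18.3 ± 4.59 CPM, the proteasome chaperone Psmd10 at 79.1 ± 20.9 and 39.0 ± 8.21 CPM and Tmed4, of the secretory pathway, at 199 ± 35.3 and 115 ± 18.7 CPM. Both groups include the 5 sets of differing identity transcripts.

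The fixed lists that did not pass under knockdown in the fit of all sets are given by their median log2 change and camera adjusted p, with the members of smallest p, none of which passed in limma. The p53 targets had a median of 0.28 (0.0584), with Pmaip1 at -2.39 and Btg2 at -1.81, and the cell cycle inhibitors -0.25 (0.229), with Cdkn2c at 1.35 and Cdkn2b at -3.55. Glycolysis and hypoxia genes had -0.22 (0.0824), with Aldoc at -2.65 and P4ha2 at -0.93. Integrins had 0.08 (0.229), with Tln1 at 0.76 and Itga6 at 1.05, extracellular matrix genes 0.16 (0.264), with Efemp1 at -2.63 and Lamc1 at 0.49, and mesenchymal genes 0.29 (0.283), with Zeb2 at 0.96 and Axl at 1.42. TGF-beta targets had -0.25 (0.232), with Junb at -1.26, and interferon genes -0.17 (0.232), with Bst2 at -1.31 and Irf7 at -1.04. RAS and MAPK genes had -0.06 (0.289), with Spry1 at -1.64, NRF2 targets -0.12 (0.818), with Me1 at -0.86, and YAP and TEAD targets -0.22 (0.837), with Fjx1 at -1.90 and Ankrd1 at -1.48. Cholesterol synthesis genes had -0.18 (0.449), the integrated stress response -0.14 (0.449) with Vldlr at -2.12 and Pycr1 at -0.79, and the unfolded protein response 0.01 (0.468) with Ssr1 at 0.58 and Hyou1 at 0.56. Ribosomal proteins had -0.12 (0.360), with Rpl26 at -1.26 and Rpl34 at 1.64, histones 0.02 (0.469), with Hist2h4 at 0.68 and Hist1h2bc at -0.65, and basal pancreatic cancer genes 0.01 (0.949), with Sprr1a at -2.27 and S100a14 at -1.56, a mean of -0.11 and a test direction down. Matrix proteases had -0.12 (0.959, test direction up), with Plat at -1.82 and Mmp14 at 0.75. The fibroblast markers had a median of -0.07, a mean of 0.56 and a test direction up (0.522), with Pdgfrb at 1.19. Of markers of hepatocytes, lung epithelium and acinar cells, Apob was at -2.31, Apoa1 at 0.15, Ager at 0.34, Aqp5 at -0.37 and Cela1 at 0.37. Several of these values were smaller with the 5 sets of differing identity transcripts left out, among them Cdkn2b, itself 1 of those transcripts, at -0.88, Axl at 0.34, Spry1 at -0.28, Me1 at -0.15, Sprr1a at -0.60 and Apob at -0.78, and the sign turned for Irf7 (0.09) and Hist1h2bc (0.37). Without lines 6-3 and 13-2 it turned for Aqp5 (0.14) and Apoa1 (-0.07), and that of Apoa1 also without 6-3 alone (-0.01) or G45-2 (-0.02).

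With the 5 sets of differing identity transcripts left out, 10 of these lists passed camera. RAS and MAPK genes had a median of -0.65 (adjusted p = 2.17e-06), glycolysis and hypoxia genes -0.51 (9.48e-08), ribosomal proteins -0.30 (9.70e-06) and TGF-beta targets -0.58 (4.61e-05). The cell cycle inhibitors had -0.41 (0.0235), the integrated stress response -0.24 (0.0255), the matrix proteases -0.20 (0.0255) and the p53 targets -0.20 (0.0190), and the unfolded protein response 0.27 (0.0269) and cholesterol synthesis genes 0.28 (0.0235). None of the 10 held with an estimated correlation in that fit (smallest adjusted p = 0.197). The direction was not stable for p53 targets, which passed upward without the second 42-2 set (0.36), 6-2 (0.37), 6-3 (0.34) or G45-2 (0.41), or for cholesterol synthesis genes, which passed downward without G45-2 (-0.39). The matrix proteases and cholesterol synthesis genes did not pass once the second 42-2 set was also left out.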
